A study of Homo sapiens with 3 samples.

How the data were processed

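Gene expression was measured in HepG2 cells, an established human liver cancer line, on 3 single-colour Agilent arrays. The arrays carried RNA of untreated cells, of cells given an extract labelled AP and of cells given an extract labelled AP20. Per the labels, the extracts were added at 0.01% to cells seeded 24 h earlier and were left on for 24 h. RNA was isolated from 3 cultures pooled per group, so each group had 1 array and the spread between cultures could not be measured. The 3 arrays shared 1 slide and 1 scan, so slide and scan did not separate the groups.

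The authors deposited 1 scanner output per array, whose values are fluorescence intensity (Cy3). Per the file headers, they were made with Agilent Feature Extraction 11.5.1.1, which subtracted the background and removed a spatial trend within each array, and no normalization between arrays was applied. The deposited values per probe also come as 1 series matrix, in intensity on a linear scale. These values matched the scanner's processed signal averaged over the spots of each probe to within 1% in 99.5% of its 50599 rows, and they were neither normalized between arrays nor centred. Probe positions in the files refer to the genome build hg19. No genome sequence was used, so whether a probe also binds transcripts of related genes was not checked. Gene symbols were updated through a table of RefSeq accessions, which matched 28174 of the 50599 probes.

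The processed signal of 58717 non-control spots per array was put on the log2 scale, and the 75th percentile of the array was subtracted. Spots that the scanner software had marked as outliers were left out, which left 29 probes with no spot. Spots of a probe were averaged, and each of 36332 genes was represented by its brightest probe over the 3 arrays. A gene was called measured in a comparison when that probe was well above background by the scanner software's own call on both arrays. No non-control spot was saturated. Where a probe was well above background on 1 array of a pair, only a lower bound of the fold was given, computed against the dim array's own value for the probe or the lowest signal among its probes well above background, whichever was higher. Where the probe's own value was the higher, as for CXCL8 and NR1H4, the result is a plain difference from a dim value and no minimum.

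Depth on an array is set by signal over background. On the untreated, AP and AP20 arrays 72.1%, 71.5% and 68.8% of spots were well above background. Among the 902 probes with 10 spots each, the median spread between spots was 0.04, 0.07 and 0.04 (SD, log2) on the 3 arrays, and it was 0.29, 0.32 and 0.26 in the dimmest 10% of these probes. It was taken over the 775, 767 and 748 of these probes with at least 5 unmarked spots well above background. This spread covers technical error within an array only. The error given with a single gene, called spot SE, is that of a difference between probe means. It was taken from the spread of these replicated probes at a like brightness, divided by the square root of the number of spots of the gene's probe, so a probe with 10 spots has a smaller one than an equally bright probe with 1 spot.

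The comparisons were AP minus untreated, AP20 minus untreated and AP20 minus AP, each as a log2 difference per gene. With 1 array per group no test between groups was possible, and the number of arrays limits the precision of every value. A difference of at least 2-fold was counted. For 36 gene lists with 793 entries, of which 786 matched a gene on the array, the median difference of the measured members was taken relative to the median of all measured genes. It was ranked among 10000 random lists of the same size, drawn to match the members over 20 bins of expression. A list was said to stand apart when its percentile was below 2.5 or above 97.5, which is a description of these arrays and not a test. The lists covered NRF2, AHR, PXR and CAR, ATF4, p53, NF-kB, interferon, HIF1, TGF-beta and immediate early genes, the unfolded protein, heat shock and acute phase responses, metallothioneins, DNA replication, mitosis and apoptosis. They also covered hepatocyte identity, coagulation and complement, cholesterol, fatty acid, bile acid, glucose, amino acid, glutathione and iron metabolism, oxidative phosphorylation, ribosomal proteins, autophagy, the proteasome, housekeeping genes and markers of fibroblasts, leukocytes, endothelium and non-hepatic epithelium.

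The groups, lists, threshold, alternatives and the rule for naming genes were fixed before the data were examined, except where stated. How list symbols were matched to genes on the array was extended after the data were seen. The rule took, per comparison, the 10 genes with the largest positive and the 10 with the largest negative difference among named genes above background on all 3 arrays, above the 25th percentile of level and with other probes of the gene going the same direction. It further took the 4 members of each list with the largest difference, list members with a bound of at least 2-fold, the 4 largest bounds per direction, and a fixed set of 14 genes. Other genes, named to spell out a list count, were chosen after their values were seen.

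Alternatives were normexp background correction with an offset of 50, quantile and cyclic loess normalization, 2 other scaling points (not counted for list medians, which a constant per array cannot move), no filter or a stricter filter on dim probes, the median of a gene's probes, the deposited value table, keeping outlier spots, unmatched random lists, and thresholds of 1.5-fold and 3-fold. Scaling on 8 spike-in probes, not counted for lists either, was chosen after the data were seen. The procedure was tested on simulated data in which 200 of 26478 genes were shifted, with a spot SD of 0.1, below that of dim probes. It recovered 98% of the genes shifted 2.5-fold and 100% of those shifted 4-fold, and placed 3% of 200 unshifted lists apart. With so small an SD it does not measure how many unshifted genes pass by chance. Arrays with no change but 1 common control were simulated 100 times from the spread between replicated spots. That spread was taken from unmarked spots above background, a choice made after the use of all spots had given 771 genes by chance, more than were observed.

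Calculations used R 4.3.3 with limma 3.58.1 and data.table (version 1.17.8), and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.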

Results

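RNA from HepG2 cells was measured on 3 arrays, 1 for untreated cells, 1 for cells given AP and 1 for cells given AP20, both extracts at 0.01% for 24 h. The series title names an extract of Andrographis paniculata, a medicinal plant, and an extract of it enriched in andrographolide, the plant's best-known diterpenoid lactone. The labels do not expand the codes AP and AP20. No group had a replicate array, so none of the differences below has a replicate check, and the spot SE given with some of them is technical. Of 36332 genes, 26478 were well above background on the untreated array, 26256 on the AP array and 25275 on the AP20 array. The 75th percentile of signal was 706, 733 and 491 on these arrays, in that order, before scaling.

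The comparison of AP20 with untreated cells asks which genes differed after 24 h with this extract. As lists, NRF2 targets, ATF4 targets and heat shock genes stood apart on the higher side on the AP20 array. DNA replication and mitosis genes stood apart on the lower side, and not every member of a list followed its median. HMOX1, which encodes the heme-degrading enzyme heme oxygenase 1, was 28.3-fold higher (spot SE 0.015 on the log2 scale, over 10 spots). AKR1B10, an aldo-keto reductase gene, was 70.1-fold higher (spot SE 0.18), and DDIT3, which encodes the stress transcription factor CHOP, was 15.1-fold higher (spot SE 0.06). MCM2, which encodes a subunit of the replicative helicase, was 5.53-fold lower (spot SE 0.05), and PLK1, which encodes a mitotic kinase, was 5.83-fold lower (spot SE 0.06). Of 24174 measured genes, 3376 were at least 2-fold higher and 2661 at least 2-fold lower, together 25.0%.

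The probe for HMOX1 lies on chromosome 22 at 35790122 to 35790181 in hg19, that for AKR1B10 on chromosome 7 at 134225799 to 134225858, that for MCM2 on chromosome 3 at 127340805 to 127340864 and that for PLK1 on chromosome 16 at 23700970 to 23701212. Of the 36 lists, 10 stood apart from random lists on the AP20 array, 7 on the higher side and 3 on the lower side, where 1.8 would if members were drawn at random. Random lists do not mimic genes that vary together, so this count is not a test.

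NRF2 targets, the genes of the antioxidant response, had a median 1.12 above that of all genes on the log2 scale (percentile 100). Of 25 measured members, 15 were at least 2-fold higher and 0 at least 2-fold lower. OSGIN1 was 62.3-fold higher, SLC7A11, which encodes a cystine transporter, 24.2-fold, TXNRD1, which encodes thioredoxin reductase, 9.63-fold and FTL, which encodes the ferritin light chain, 7.69-fold. NQO1, another commonly used NRF2 target, differed by 0.62 on the log2 scale and GCLM, a subunit of the enzyme that starts glutathione synthesis, by 1.24.

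Targets of ATF4, the transcription factor of the integrated stress response, had a relative median of 1.03 (percentile 100), with 14 of 23 measured members at least 2-fold higher and 0 lower. CHAC1, which encodes a glutathione-degrading enzyme, was 14.1-fold higher and PPP1R15A, which encodes a phosphatase subunit that ends the response, 6.06-fold higher. ATF3 was 4.97-fold higher by its brightest probe, but its 4 probes ranged from 0.17 to 2.31 on the log2 scale. SLC7A11 belongs to both this list and the NRF2 list. Of 18 heat shock genes, 9 were at least 2-fold higher and 0 lower, with a relative median of 0.88 (percentile 100). The chaperone genes HSPA1A, HSPB8 and HSPA1B were 7.66-fold, 4.71-fold and 4.21-fold higher. The unfolded protein response list of the endoplasmic reticulum went both ways, with 6 of 20 members at least 2-fold higher, 5 lower and a relative median of 0.06. DNAJC3 was 5.21-fold higher and DNAJB9 3.62-fold higher, whereas the 5 lower genes were the chaperone gene HSPA5 (−1.04), PDIA4, PDIA6, SDF2L1 and CRELD2.

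The autophagy and lysosome, proteasome and immediate early lists stood apart on the higher side as well. Of 23 autophagy and lysosome genes, 10 were at least 2-fold higher and 1, the lysosomal protease gene CTSB, at least 2-fold lower, with a relative median of 0.75 (percentile 100). SQSTM1, which encodes the autophagy receptor p62, was 11.2-fold higher, MAP1LC3B 6.14-fold and GABARAPL1 5.65-fold. Of 24 proteasome genes, 6 were at least 2-fold higher and 0 lower, with a relative median of 0.53 (percentile 100), among them PSMC4 (3.97-fold) and PSMB3 (3.45-fold). Of 23 immediate early genes, 11 were at least 2-fold higher and 1, the phosphatase gene DUSP6, lower, with a relative median of 0.74 (percentile 100). CCN2 was 10.8-fold higher, ZFP36, which encodes an mRNA-destabilizing protein, 6.48-fold, and NR4A1, above background on the AP20 array alone, at least 3.33-fold.

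Genes of cholesterol synthesis and uptake under the transcription factor SREBP2 had a relative median of 0.78 (percentile 100). Of 25 members, 12 were at least 2-fold higher. STARD4, which encodes a sterol carrier, was 5.09-fold higher and IDI1, which encodes isopentenyl diphosphate isomerase, 4.21-fold higher. PMVK, which encodes phosphomevalonate kinase, was the 1 member at least 2-fold lower (−1.93).

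DNA replication genes had a relative median of −1.82 (percentile 0), and 21 of 25 were at least 2-fold lower, 0 higher. POLA1, which encodes the catalytic subunit of DNA polymerase alpha, was 5.38-fold lower, FEN1, which encodes a flap endonuclease, 5.08-fold and UHRF1 4.97-fold. Mitosis genes had a relative median of −1.73 (percentile 0), and 19 of 24 were at least 2-fold lower, 0 higher. KIF20A, which encodes a mitotic kinesin, was 4.96-fold lower, CDC20, which encodes an activator of the anaphase-promoting complex, 4.75-fold and TOP2A 4.43-fold. Oxidative phosphorylation genes had a relative median of −0.58 (percentile 0.675), and 29 of 31 lay below the median of all genes. Of them 3 were at least 2-fold lower, among them CYC1 of complex III (3.20-fold) and NDUFV1 of complex I (2.46-fold), and 0 were at least 2-fold higher.

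**Figure D1:**
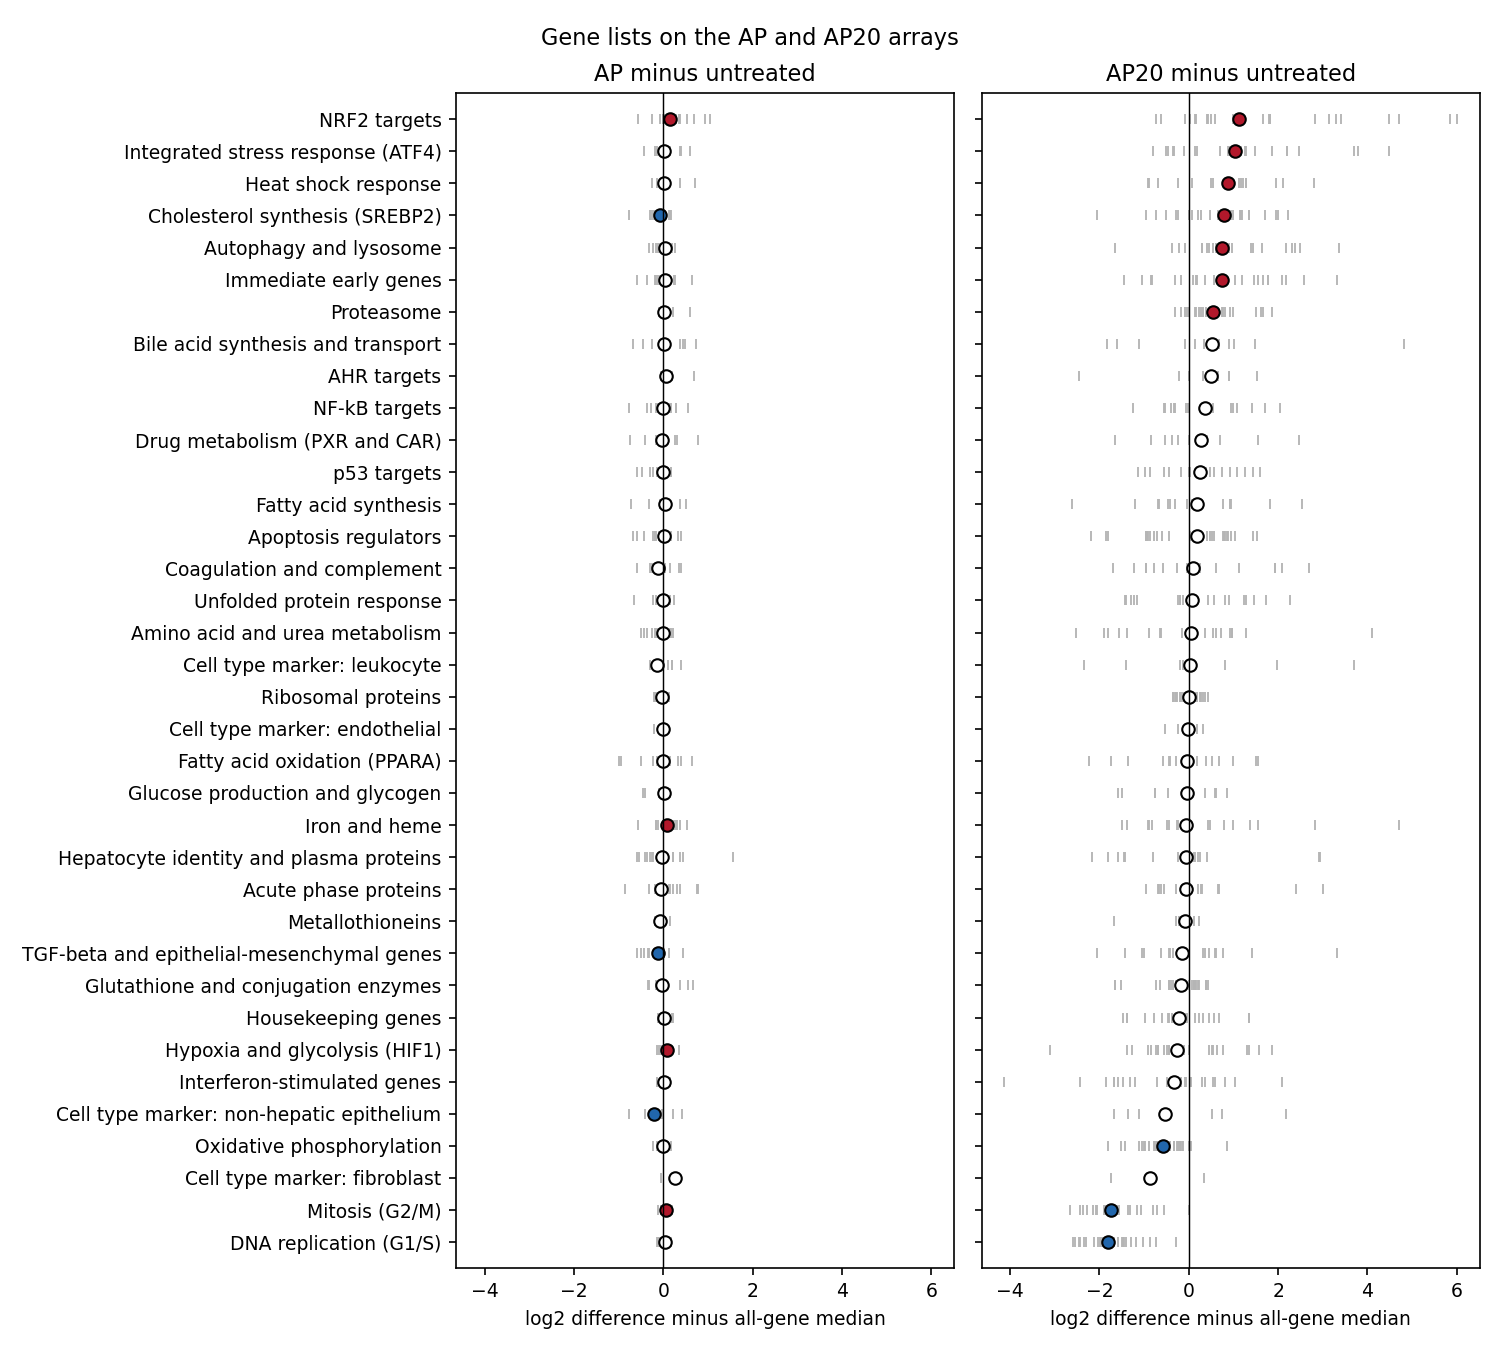
Differences from the untreated array for 36 gene lists, with AP on the left and AP20 on the right; the horizontal axis is the log2 difference minus the median of all measured genes, grey ticks are list members and circles are list medians, red where the list stood apart on the higher side of random lists, blue where on the lower side and white otherwise. On the AP20 array NRF2 targets sat at 1.12 and DNA replication genes at −1.82, while on the AP array they sat at 0.14 and 0.03.

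The liver-specific lists did not stand apart, and 8 of 27 hepatocyte genes on the array were not above background in untreated cells. The 70.4% that were lay close to the share of all genes, 26478 of 36332, which does not tell what share of liver genes to expect. Of 16 measured hepatocyte genes, 2 were at least 2-fold higher and 5 lower, with a relative median of −0.07. Every list median of AP20 minus untreated is given relative to the median of all genes, 0.12, whereas values of single genes are not. A list median just below 0 can thus be above 0 before that subtraction. Albumin (ALB) was 8.20-fold higher, from a dim signal 4.59 below the array's 75th percentile on the log2 scale in untreated cells, and the transcription factor gene FOXA1 8.40-fold higher, whereas APOM was 4.15-fold lower and NR5A2 3.20-fold lower, and APOC1, FOXA2 and AHSG were the other lower members. The plasma protein genes TF, AFP and AMBP were above background on the AP20 array but not on the untreated array, at least 15.5-fold, 2.83-fold and 2.41-fold higher. Of 17 acute phase genes, 2 were at least 2-fold higher, IL6R (3.12) and CFB (2.52), 0 were lower, and the relative median was −0.07. SAA2, FGG and SAA4 were above background on the AP20 array but not on the untreated array, at least 6.12-fold, 5.70-fold and 2.66-fold higher. Coagulation and complement genes had a median of 0.10, with 5 of 18 higher, C1S (2.81) and C2 (2.22) first, and 2 lower, CFI and F10. The bile acid list had a median of 0.52 (percentile 97.3), with 4 of 14 higher and 2 lower, and NR1H4, which encodes the bile acid receptor FXR, was 30.6-fold higher. Among amino acid and urea genes, 5 of 20 were higher and 5 lower (median 0.05), with CBS 18.8-fold higher and the urea cycle genes OTC and CPS1 5.25-fold and 3.22-fold lower.

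Drug metabolism genes under PXR and CAR had a median of 0.26, with the efflux pump gene ABCB1 (2.60) and ALAS1 (1.67) higher and GSTA2 (−1.52) lower among 13. CYP3A4, above background on the AP20 array alone, was at least 2.99-fold higher. AHR targets had a median of 0.50 (percentile 96.3), with TIPARP, AHRR and CYP1A2 of 9 at least 2-fold higher and LRAT lower, and the classical target CYP1A1 differed by 0.78. Glutathione and conjugation genes had a median of −0.18, with 0 of 23 at least 2-fold higher and GSTA4, GSTA2 and GPX1 lower. Iron and heme genes had a relative median of −0.05, with 5 of 20 higher and 2 lower, and 3 of the higher members, HMOX1, FTL and FTH1, belong to the NRF2 list too. Metallothionein genes had a relative median of −0.09 (0.04 before subtraction of the median of all genes), and 1 of 10, MT1F, was at least 2-fold lower.

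Interferon-stimulated genes were lower in 9 and higher in 2 of 22 members, with a median of −0.32 that did not stand apart. IFIT1 was 16.1-fold lower and OAS3 5.01-fold lower, whereas IRF7 was 4.64-fold higher. NF-kB targets had a median of 0.36 (percentile 96.5), with 6 of 18 higher, RELB (2.16) and NFKB2 (1.83) first, and 1, TRAF1, lower. NFKBIA, which encodes the inhibitor of NF-kB, differed by 0.57. CXCL8, not well above background on the untreated array, was 2.38-fold higher against its own dim value there (spot SE 0.39). Of 20 p53 targets, 5 were higher, among them TP53INP1 (1.71) and CDKN1A (1.04), and FDXR was lower, with a median of 0.25 (percentile 95.6). Apoptosis regulators had a median of 0.18 (percentile 96.4), with 5 of 30 higher, CASP9 (1.66) first, and BCL2 (−2.07, its other probe −0.53), BIRC5 and CASP10 lower, though the 2 probes of CASP10 above background lay at −1.69 and 1.14.

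Among the remaining metabolic lists, hypoxia and glycolysis genes had a median of −0.26, with 4 of 27 higher, VEGFA (1.98) first, and CA9 (−2.99), LDHA and ENO1 lower. Fatty acid synthesis genes had a median of 0.19, with 5 of 20 higher, LPIN1 (2.66, its other probe 0.72) first, and DGAT2 (−2.50) and ACACB (−1.09, its other probe −0.15) lower. For fatty acid oxidation the relative median was −0.03, with 3 of 19 higher, PPARA (1.66) first, and ACAA2 (−2.10), HADH and PLIN2 lower. Glucose and glycogen genes had a relative median of −0.04, with SLC37A4 and PYGL of 11 lower. TGF-beta and epithelial-mesenchymal genes had a median of −0.15, with CCN2 and ZEB1 of 18 higher and TWIST1 and TGFBI lower. Of 29 ribosomal protein genes 0 differed by 2-fold (median 0.01). Housekeeping genes had a median of −0.23, and 15 of 20 lay within 2-fold. VCP (1.48) and POLR2A (1.46) were higher, and 3 were lower, the tubulin genes TUBA1B and TUBB among them. Markers of fibroblasts (3 measured, median −0.87), leukocytes (9, 0.02), endothelium (4, −0.03) and non-hepatic epithelium (7, −0.52) did not stand apart, and single markers went both ways, with CD68 14.2-fold and SFN 4.93-fold higher but CORO1A 4.65-fold, COL1A1 3.06-fold and MUC1 2.95-fold lower (log2 difference of its other probe 0.12).

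Outside the lists, the largest positive differences by the naming rule were those of HKDC1, which encodes a hexokinase (6.85, its other probe 1.42), AKR1B15 (5.92), EID3 (5.85), the long noncoding RNA MIR31HG (5.38) and the interferon gene IFNE (5.36). AKR1B15 lay close to AKR1B10 (6.13), and whether its 1 probe also binds AKR1B10 transcripts was not checked, so it may not be a separate difference. The probes for MIR31HG and IFNE lie near each other on chromosome 9, at 21454716 to 21454775 and 21481102 to 21481161. The largest negative ones were those of RPRML (−4.51, its other probe −1.14), LINC00698 (−4.47, its 4 probes above background from −5.29 to −1.68), the keratin gene KRT23 (−4.15), CIB4 (−4.11) and NUDT14 (−4.08), and the transcription factor gene SOX4 lay at −3.95. Among genes above background on 1 of these arrays, the thrombin receptor family gene F2RL2 was at least 92.6-fold higher and the organic anion transporter gene SLCO2B1 at least 33.8-fold higher, while the antiviral deaminase gene APOBEC3G was at least 50.5-fold lower and WNT16 at least 21.3-fold lower.

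Of 1520 genes with a difference of 2-fold and another probe above background, 85.6% had that probe going the same direction, and 49.8% had it at 2-fold too. Scaled on the spike-in probes instead, 2407 genes were higher and 3572 lower, so the share on the higher side went from 55.9% to 40.3%. That scaling moved the median of all genes from 0.12 to −0.08, and list medians, given relative to it, do not depend on such a shift.

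**Figure D2:**
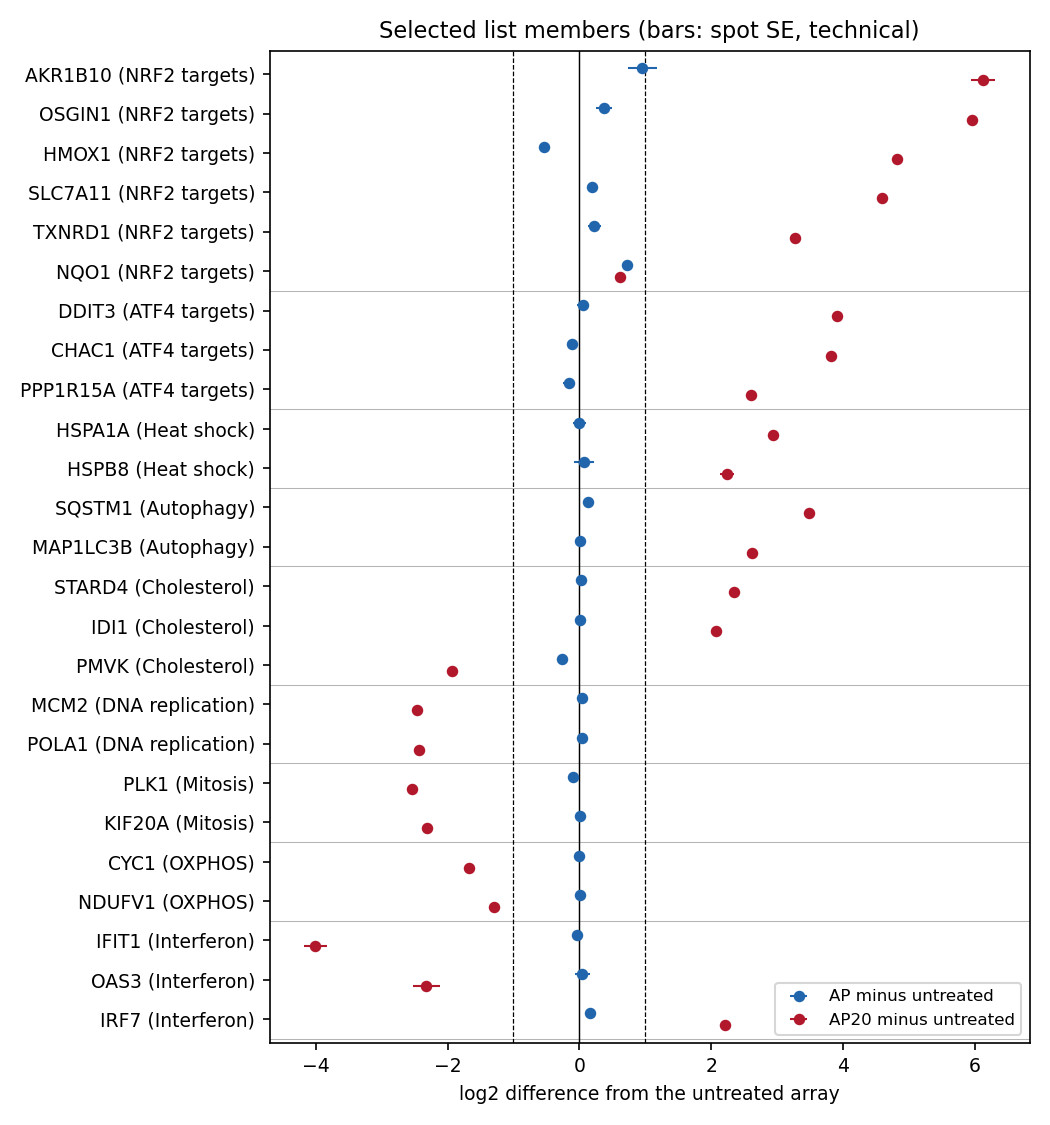
Log2 difference from the untreated array for selected members of the gene lists, AP in blue and AP20 in red; points are the brightest probe of each gene, bars are spot SEs (technical, 1 array per group) and dashed lines mark 2-fold. HMOX1 sat at 4.82 on the AP20 array and at −0.54 on the AP array, and MCM2 at −2.47 and 0.04.

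The comparison of AP with untreated cells asks the same question of the other extract. Most genes lay within 2-fold, including nearly all members of the lists. NRF2 targets were a little higher together, with a median 0.14 above that of all genes (percentile 100) and 22 of 26 members above the median of all genes. Among them AKR1B10 differed by 0.96 (spot SE 0.22), NQO1 by 0.72 (spot SE 0.07) and FTL by 0.55, while HMOX1 differed by −0.54 (spot SE 0.02). Of 25074 measured genes, 146 were at least 2-fold higher and 194 at least 2-fold lower, together 1.36%.

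Without its 3 highest members the NRF2 list kept a relative median of 0.13 (percentile 100). Hypoxia and glycolysis genes had a relative median of 0.09, with 22 of 27 above the median of all genes, PFKFB3 (0.39) first. Iron and heme genes had 0.09, with FTL, FTH1 and HMOX1 shared with the NRF2 list, and mitosis genes 0.06. On the lower side stood cholesterol synthesis genes (−0.08, PMVK at −0.26), TGF-beta genes (−0.12, CCN2 at −0.57) and non-hepatic epithelium markers (−0.22, KRT5 at −0.74). CCN2 and KRT5 were dim, with spot SEs of 0.43 and 0.42. These 7 lists stood apart from random lists, where 1.8 would if members were drawn at random. Lists share members and random lists do not mimic genes that vary together, so this count is not a test of the extract. The NRF2 and HIF1 lists stood apart under all 9 alternatives that can move a list, whereas each of the other 5 lost that place under at least 1 alternative. ATF4 targets (0.02), heat shock genes (0.02), proteasome genes (0.01), immediate early genes (0.03), autophagy and lysosome genes (0.04), DNA replication genes (0.03) and oxidative phosphorylation genes (0.00), which stood apart on the AP20 array, did not on the AP array.

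The largest positive differences by the naming rule were those of GABRQ (2.58, its other probe 0.22), CIMIP2B (2.46), MCEMP1 (2.33), the developmental gene HOXB2 (2.04, its other probe 0.67) and ZNF319 (1.89). PPP3R1, which encodes the regulatory subunit of calcineurin, lay at 1.36 (its other probe 0.07), DLST, which encodes a subunit of the oxoglutarate dehydrogenase complex, at 1.27 (spot SE 0.07) and the nucleolar protein gene NPM3 at 1.23 (spot SE 0.06). The largest negative ones were those of the glutamate receptor subunit gene GRIK5 (−2.56), WHR1 (−2.29), MAS1L (−1.94) and YPEL4 (−1.94). SPTLC2, which encodes a subunit of the enzyme that starts sphingolipid synthesis, lay at −1.67 (spot SE 0.18). Among bounds, RAB39A was at least 15.6-fold higher and VLDLR, which encodes a lipoprotein receptor, at least 2.51-fold higher, while PGLYRP2 was at least 8.12-fold lower and the acute phase gene SAA1 at least 2.39-fold lower.

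Of the 340 genes at 2-fold, 84.1% lay among the dimmest 40% of genes and 9 genes among the brightest 20%, and another probe went the same direction in 24 of 47 genes. Normexp correction left 28 higher and 30 lower, GABRQ at 1.25 and GRIK5 at −1.16, and spike-in scaling turned the split to 306 higher and 130 lower.

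The comparison of AP20 with AP asks how the extracts differed at the same dose and time, and it shares the AP20 array with the comparison of AP20 with untreated cells, so a like direction in both is not independent evidence. HMOX1 was 41.0-fold higher on the AP20 array than on the AP array, AKR1B10 36.1-fold, SLC7A11 21.2-fold and DDIT3 14.6-fold, while MCM2 was 5.70-fold lower and PLK1 5.47-fold lower. NQO1 differed by −0.10 on the log2 scale between the extracts. Of 24058 measured genes, 3227 were at least 2-fold higher on the AP20 array and 2721 lower, together 24.7%.

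NRF2 targets had a relative median of 1.34, with 13 of 25 higher by 2-fold on the AP20 array and 0 lower, ATF4 targets 0.81 (11 of 23 higher) and heat shock genes 0.74 (6 of 18 higher). Cholesterol synthesis genes had 0.81 (12 higher, PMVK lower, of 25), autophagy and lysosome genes 0.67 (9 higher, 1 lower, of 23), immediate early genes 0.66 (10 higher, 1 lower, of 23) and proteasome genes 0.46 (5 of 24 higher). DNA replication genes had −1.85 (21 of 25 lower), mitosis genes −1.80 (19 of 24 lower) and oxidative phosphorylation genes −0.63 (3 lower, NDUFA4 higher, of 31). p53 targets had 0.41 (percentile 99.4), with TP53INP1 (1.79), TNFRSF10B, GDF15, CDKN1A and ZMAT3 of 20 higher, and apoptosis regulators 0.32 (percentile 99.6), with 5 higher and 4 lower. NF-kB targets had 0.44 (percentile 98.4, RELB at 1.97), hepatocyte genes −0.59 (percentile 0.35, APOM at −2.08 but ALB at 2.78) and non-hepatic epithelium markers −0.78 (percentile 1.09, MUC1 at −1.41 but SFN at 2.30).

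Beyond the lists, HKDC1 (6.40), IFNE (5.84), MIR31HG (5.60), EID3 (5.57), AKR1B15 (4.97), IFITM10 (4.80) and NAV3 (4.78) had the largest positive differences by the naming rule, and MTHFD1, which encodes an enzyme of folate metabolism, lay at −3.68. NR1H4, not well above background on the AP array, was 54.6-fold higher on the AP20 array against its own dim value on the AP array (spot SE 0.33). In all 15 lists stood apart, 12 of them under all 9 alternatives that can move a list. The exceptions were NF-kB targets, hepatocyte genes and non-hepatic epithelium markers, and a stricter filter turned the hepatocyte median to 0.07. Spike-in scaling moved the split to 1700 higher and 4848 lower, with the median of all genes at −0.28 in place of 0.13.

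AP and AP20 were also compared for the genes they had in common against the untreated array. Of 23705 genes above background on all 3 arrays, 51 were at least 2-fold higher on both, among them ZNF319 and DLST, and 15 at least 2-fold lower on both, among them SPTLC2, where 15.2 and 20.5 would be so if the comparisons were independent. In 8 genes the directions were opposite, NPM3 among them. The comparisons share the single untreated array, and simulated arrays with no change gave 60.5 common genes on average and 84 at most, but with 126 genes at 2-fold on the AP20 side, against 5907 observed. Across genes, which are not independent replicates, Pearson's r between the differences was 0.18 and Spearman's rho 0.19, below the r of 0.51 of the simulated arrays. The covariance was 0.0504, above the 0.0268 of the simulated arrays. With 1 control array the control could not be split, so how much of the overlap comes from it was not settled.

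**Figure D3:**
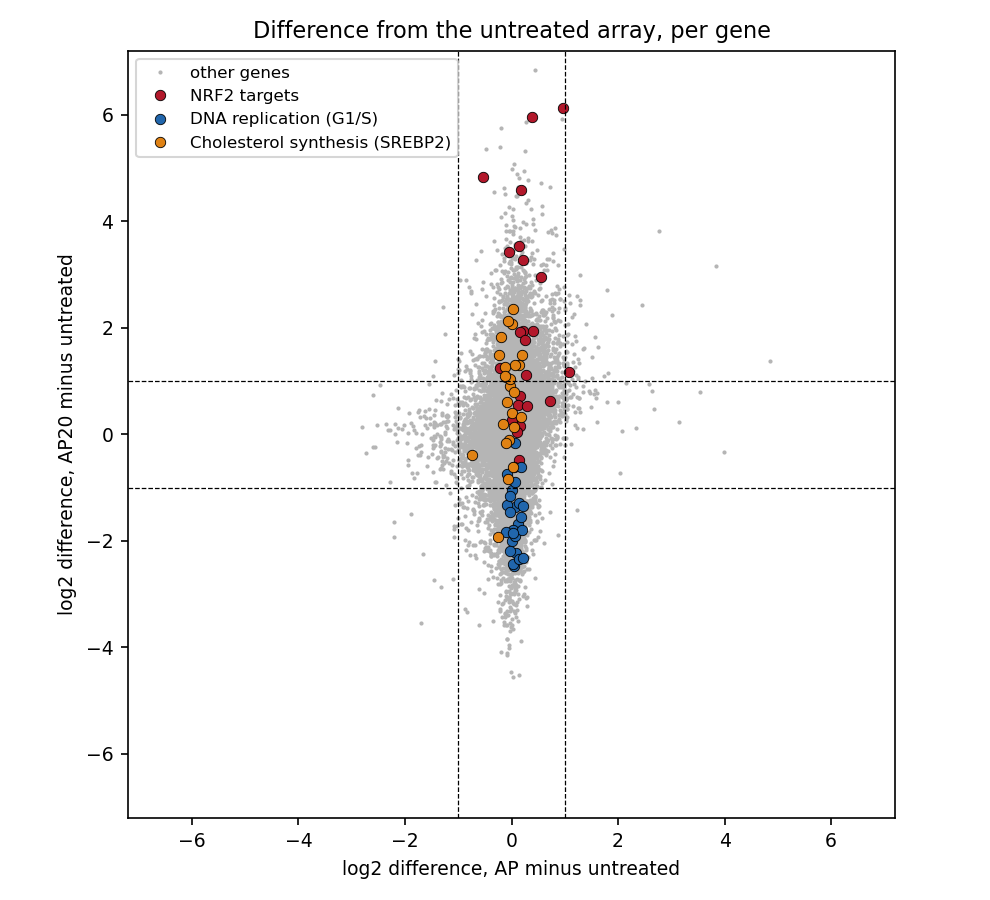
Log2 difference from the untreated array for each of 23705 genes above background on all 3 arrays, AP on the horizontal and AP20 on the vertical axis; NRF2 targets are red, DNA replication genes blue, cholesterol synthesis genes orange, other genes grey, and dashed lines mark 2-fold. AKR1B10 sat at 0.96 and 6.13, and the cloud was narrow on the AP axis, where 294 of these genes reached 2-fold, against 5907 on the AP20 axis.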

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

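The patterns were seen before any test below was chosen. The expected values were written before the tests on the 1st and 2nd patterns were run, but not for the 2000-nucleotide comparison, the simulated arrays and the tests on the liver genes and their probes, which were chosen after the result was seen. The liver genes replaced an earlier 3rd pattern, the NRF2 list on the AP array, after it had been tested. These 4 results stood out because they went one way on the AP array and the other way on the AP20 array. The differences were not tested, since each rests on 1 array per group. Mitosis genes had a median of 0.0624 relative to all genes on the AP array and −1.73 on the AP20 array. The AP median was small and stood apart from random lists under 5 of the 9 alternatives that can move a list, with percentiles down to 77.3. Cholesterol synthesis genes had −0.0807 on the AP array and 0.78 on the AP20 array. HMOX1 differed by −0.54 on the AP array and by 4.82 on the AP20 array. NPM3 differed by 1.23 on the AP array and by −1.42 on the AP20 array.

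The 1st pattern weighed is that 25.0% of the genes differed by 2-fold on the AP20 array. Noise of single spots would have sent other probes of these genes either way, but 85.6% of 1520 genes had another probe going the same direction. Degraded RNA in the AP20 sample would have lowered the probe nearer the 5′ end. Over 2651 transcripts with probes at least 500 nucleotides apart the 5′ probe lay 0.0131 higher in the median (95% interval −0.017 to 0.054). At 2000 nucleotides, over 1062 transcripts, it lay 0.27 higher (0.21 to 0.35), a trend opposite to such degradation. In AP minus untreated that median was −0.04. The AP20 array thus had a shift with probe position at that distance, whose cause was not tested. A trend with intensity from the weaker signal of the AP20 array is argued against too, since 91.1% of the 6037 genes kept 2-fold and direction after cyclic loess. That step leaves the scatter of dim probes in place, so it cannot tell how much such scatter adds. Normexp correction, which shrinks differences of dim probes, kept 63.7% of the genes. An effect of the extract may account for the 1st pattern, but a difference between the pooled cultures from other causes stays open, as 1 array per group cannot separate them.

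The 2nd pattern is that 340 genes differed by 2-fold on the AP array. Noise of single spots may account for a large part of them, since 51.1% of 47 genes had another probe going the same direction, close to an even split. Simulated arrays with no change gave 187 genes on average and 229 at most, against 294 observed among genes above background on all 3 arrays. These simulations drew noise from spots above background only, a choice made after all spots had given 771 genes on average. The simulation therefore cannot decide whether more genes reached 2-fold than noise would give. Whether deviating spots of the untreated array add to the 2nd pattern cannot be told apart, since 40.1% of the 294 genes also lay 1.5-fold from the untreated array in the same direction on the AP20 array, between the bounds set beforehand. An effect of the extract on some of these genes stays open.

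The 3rd pattern is that 8 of 27 hepatocyte genes were not well above background on the untreated array, AFP, APOC3, APOH, TF, TTR, AMBP, RBP4 and HNF4A, although HepG2 is known for making several of these proteins. As a count this lay close to the share of all genes above background, with 70.4% of the list against 26478 of 36332 genes. That share mixes named genes with others, as 20602 of the 36332 had a reference symbol. It therefore cannot tell how many genes of this list a liver line should show. Low sensitivity of that array is argued against, as 72.1% of its 58717 spots were well above background. Whether probes do not work stays open, as 3 of the 8 genes, AFP, TF and AMBP, were above background on the AP20 array, but AFP and AMBP close to its floor. Cells other than the labelled line could be a source. Of 10 markers of non-hepatic epithelium, 80% were above background on that array, also not far from the share of all genes. SFN lay 6.20 and KRT7 4.28 above the array's 75th percentile on the log2 scale. Such cells cannot be told apart from HepG2's own expression because no reference array of the line was analysed here. No biological explanation was tested, since the design gives none.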

How the results depend on the processing

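Scaling on spike-in probes was chosen after the data were seen, and the other alternatives were planned. In comparisons with AP20, the 10 lists that stood apart from untreated and 12 of the 15 that stood apart from AP did so under all 9 alternatives that can move a list. For single genes taken by the naming rule, 5018 values moved by less than the spot SE and 1210 by more, and 0 of the 320 differences of at least 2-fold changed sign. For lists, leaving out alternatives that cannot move the median, 783 values stayed within the spread of random lists, 76 moved, and 2 of the 32 medians that stood apart changed sign, and for gene counts 58 stayed within 1.5 times and 33 did not. The 2 medians were the hepatocyte median of AP20 minus AP, 0.0685 under the stricter filter, and the non-hepatic epithelium median of AP minus untreated, 0.0727 with the median of probes. Of the 76 list medians that did not stand apart, 40 changed sign under some alternative and 12 came to stand apart, for example coagulation and complement in AP20 minus AP, at −0.77 with no filter. Among gene differences under 2-fold, 106 of 253 changed sign. The cause was not tested.

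Counts beyond 1.5 times the reported ones were as follows, higher before lower. Normexp gave 28 and 30 for AP minus untreated, 2036 higher for AP20 minus untreated, 2000 higher for AP20 minus AP and 18 common genes. It adds an offset of 50, which shrinks differences of dim probes, and kept 16.2% of the genes of AP minus untreated and 63.7% of those of AP20 minus untreated. With no filter on dim probes, which lets in genes near background, AP minus untreated had 2064 and 1702, AP20 minus untreated 6341 and 4006, AP20 minus AP 6026 and 4184, with 1465 common genes. The stricter filter, which measures fewer genes, gave 31 and 71 for AP minus untreated and 26 common genes. A 1.5-fold threshold gave 773 and 770, 6332 and 4762, 6195 and 4934, and 549 common genes, and a 3-fold threshold 33 and 50, 1353 and 1077, 1262 and 1100, and 10 common genes. Spike-in scaling gave 306 higher for AP minus untreated, 1700 and 4848 for AP20 minus AP, and 107 common genes, and the cause was not tested.

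Signal over background limits these data. The dimmest 20% of genes had a median of 0.33 in AP20 minus untreated and the brightest 20% −0.08. No paired analysis was possible because each group had 1 array.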

Other observations

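The families below, chosen after the data were seen, were compared between AP20 and untreated cells as medians relative to all genes. They were picked from a longer set, so they do not stand for gene families at large. That set also held zinc finger genes (0.18 over 379 genes, percentile 100, 63 higher and 26 lower). It held families near random as well, such as tubulins (−0.10, percentile 52.6) and solute carriers (0.02, percentile 85.0). Whether probes of related genes in a family also bind each other's transcripts was not checked, so members may not be separate measurements. The 4F family of cytochrome P450, which oxidizes fatty acids and leukotrienes, had a median of 3.17 over 6 genes, and 4 were at least 2-fold higher, CYP4F11 (4.40) first, while CYP4F22 lay at −0.69. Aldo-keto reductase genes had a median of 1.65 over 9 genes, with 6 at least 2-fold higher and AKR1A1 (−1.65) lower, and AKR1B10, AKR1C1 and AKR1C3, the median gene, belong to the NRF2 list too. Subunits of the V-ATPase, the pump that acidifies lysosomes, had 0.63 over 20 genes, with 7 higher and 0 lower, ATP6V0D1 (1.90) first. Genes of the DNAJ co-chaperones had 0.47 over 43 genes, with 12 higher and 3 lower, DNAJB4 (2.71) first.

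Mitochondrial ribosomal protein genes had a median of −0.92 over 76 genes, and 26 were at least 2-fold lower and 0 higher, MRPL23 (−1.86) first, whereas the cytosolic ribosomal proteins lay at 0.01. Kinesin genes had −0.78 over 34 genes, with 11 lower, KIF20A (−2.31) first, and 3 higher, KIF1B (2.10) first. Keratin genes had −0.41 over 31 genes, with 4 lower and 0 higher. Against the same untreated array, AP also had 5 keratin genes at least 2-fold lower and 0 higher (relative median −0.07). Between the extracts, AP20 minus AP had 3 lower and 3 higher (−0.18, percentile 10.5). The keratin difference is thus not particular to AP20. None of the 7 family medians of AP20 minus untreated given so far changed sign under normexp, quantile and cyclic loess normalization. Their ranges were 2.62 to 3.28 for the 4F family, 0.90 to 1.78 for aldo-keto reductases and −1.10 to −0.77 for mitochondrial ribosomal proteins. Histone genes had 14 higher and 14 lower, and their median of −0.11 changed sign.

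Above background on the untreated, AP and AP20 arrays were 6, 4 and 3 of 12 fibroblast markers, 9, 10 and 9 of 11 leukocyte markers, 6, 5 and 5 of 10 endothelial markers and 8, 8 and 7 of 10 markers of non-hepatic epithelium. Of all 36332 genes, 26478, 26256 and 25275 were above background on these arrays, in that order.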
